A study of Mus musculus with 7 samples.

How the data were processed

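The data describe single plasmacytoid dendritic cells (pDCs), an immune cell type that senses viral nucleic acids and secretes type I interferon, taken from the spleen of wild-type C57BL/6 mice. Per the labels, 2 plates hold pDCs of uninfected mice, sorted as total pDCs, and 5 plates hold pDCs of mice 36 h after infection with murine cytomegalovirus (MCMV), a herpesvirus of mice, sorted with an enrichment for cells low in LIFR, the receptor of leukaemia inhibitory factor. Each plate is 1 sample and 1 replicate. The labels do not say that plates came from separate mice, so p-values measure the spread between plates, which may be technical. Tests that permute cells within plates measure the spread between cells instead. Infection and the enrichment for LIFR-low cells coincide, so a difference between the groups holds both.

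Per the labels' protocols, single cells were sorted into plates with lysis mix and external spike-in RNA, and cDNA was made with an oligo-dT primer and a template switching oligonucleotide that carries a well barcode and a 5-base molecular identifier; the method, FB5P-seq, reads the 5' end of transcripts. Per the submitters' processing notes, bcl2fastq, STAR 2.5.3a, HTSeq 0.9.1 and the genome build GRCm38 were used. The role and settings of each tool are not given in the sources used here. The authors deposited a count table of 13686 genes in 591 cells, in which a value is the number of different identifier sequences seen for a gene in a cell. These counts are whole numbers from 0 to 1024, which is the number of possible 5-base sequences, and 12 values sit at 1024. The median of the values above 0 was 85.0, so a value does not number the captured molecules, and it saturates for abundant genes, which compresses their fold changes. The design fixed before the data were examined assumed molecule counts; the count test was kept because the values are unscaled whole-number counts, and a correction for saturation was added as an alternative. Of the values above 0, 32.0% lay under 20 identifiers. Every gene in the table has a value in at least 3 cells and every cell has at least 752 genes, and the filter behind this is not given in the sources used here. The table has 0 spike-in rows and 0 rows that name no gene.

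The authors also deposited the fluorescence intensity of each cell in the index sort for LIFR, BST2, CD11c, CD11b, a lineage antibody cocktail and a viability dye, with forward and side scatter. Per the file headers these intensities are compensated, and the scale is not given in the sources used here. Plates were assigned from the cell names in both tables, and 0 columns were left without a sample. No cell annotation was used, and the planned comparison of an annotated cell state with the rest was therefore not run.

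Cells with at least 250 genes were kept, which removed 0 of the 591 cells; no doublet caller was run because wells were sorted as single cells. Counts were summed per plate and tested with edgeR 4.0.16 (R 4.3.3) using TMM factors, its expression filter, the quasi-likelihood test and Benjamini-Hochberg adjustment, with an adjusted p threshold of 0.05. Levels are identifiers scaled to a common plate total, on the CPM scale, given as mean ± SD over plates, and log2 changes carry their standard error (SE). A gene was taken as seen in a cell at 20 or more identifiers, a limit set after the value distribution was seen. Where a gene lay under a floor of 11.8 CPM in the uninfected group, the fold is a lower bound against that floor, which stands for 3 values of 146 identifiers, the median of such values for rarely seen genes, over the whole uninfected group. Intervals and floors cover counting error only.

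Infected plates were compared with uninfected plates using all cells, and again using only the infected cells with 0 identifiers of type I and III interferon genes. Within the infected plates, cells with 3 or more interferon identifiers were compared with cells with 0, summed per plate, with the plate as a block and the interferon genes left out of the counts. These comparisons, their tests, the gene lists and the rule for named genes were fixed before the data were examined. A comparison within the infected plates, of the cells below with the cells above the plate's median LIFR fluorescence and with the plate as a block, was added after the intensities had been seen. Named genes are the 10 with the largest positive and the 10 with the largest negative log2 change among those past the threshold, with a mean log2 CPM of at least 5 and groups that do not overlap (the same sign in every plate within infected plates), up to 4 members of each list with the smallest adjusted p past the threshold, and a fixed set of anchor genes (Lifr, Ifnb1, Ifna4, Irf7, Isg15, Siglech, Bst2, Tcf4, Ccr7, Cd86, Ly6d and Ccr9). Interferon alpha genes are near-identical copies between which reads can be split, so their single values are uncertain. Gene positions are those of GENCODE mouse release 21 on GRCm38.

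Gene lists were tested with limma 3.58.1, with camera at a preset correlation of 0.01, camera with a correlation estimated per list, and fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Each list also has a count of members past the threshold when adjusted over the list alone. Shares of cells were compared after thinning each cell to 150800 identifiers, which left out 24 uninfected and 94 infected cells, and with exact two-sided permutation tests over the 21 splits of the plates, where the smallest possible p is 0.0476. Correlations within plates are Spearman's rho. Clusters were found with scanpy 1.11.5 and igraph 0.11.9 from 2000 variable genes, 20 principal components, 15 neighbours and a resolution of 0.8.

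The count test was checked on simulated counts with 200 changed genes drawn from the fitted means and spreads. Changed genes were taken only from those with a mean level well above the floor of 11.8 CPM, with equal numbers raised and lowered. Recovery therefore does not cover genes near the floor, or a comparison where most genes move in 1 direction. For infected against uninfected plates (11526 genes) it recovered 2.99% of genes changed by 1 on the log2 scale, 47.8% of those changed by 2 and 90.9% of those changed by 4, and it called 3 unchanged genes. For the interferon-negative cells (11235 genes) recovery was 1.49%, 40.3% and 83.3%, with 6 unchanged genes called. For interferon-positive against interferon-negative cells (10313 genes) it was 0%, 0% and 15.2%, with 1 unchanged gene called. For LIFR-low against LIFR-high cells (10858 genes) it was 13.4%, 55.2% and 84.8%, with 9 unchanged genes called.

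Alternatives fixed before the data were examined were DESeq2 1.42.0, its size factors within edgeR, no scaling factors, no filter on low counts, other limits on genes per cell, thinned cells, leaving out cells with 3 or more identifiers of other-cell-type markers, leaving out each plate, other limits for an interferon-positive cell, negative cells matched on their total, and a fit without the plate block. Added after the data were seen were counting cells with 20 or more identifiers, setting values under 20 to 0, a saturation correction, taking out a trend with transcript length, leaving out infected replicates 4 and 5, and restricting infected cells to the LIFR range of uninfected cells. Scaling to spike-ins was not run because the table has 0 such rows.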

Results

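Transcripts of single splenic pDCs were counted from the 5' end on 7 plates, 2 from uninfected mice and 5 from mice 36 h after MCMV infection. The uninfected plates held 167 cells (81 and 86 per plate) and the infected plates 424 cells (83 to 87 per plate). Plate totals were 17719368 and 19410562 identifiers for uninfected plates and lay between 13576915 and 18061630 for infected plates. Cell totals ran from 59509 to 381576, with a median of 198242, and 752 to 2536 genes had a value in a cell. Each cell also had its fluorescence in the sort, so transcripts and surface proteins were measured on the same cells. The labels and the series design set infected against uninfected pDCs, and the series asks how pDCs become activated in vivo during a viral infection.

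The comparison of infected with uninfected plates asked which genes differ in pDCs of infected mice, with the enrichment for LIFR-low cells included in the difference. Infected plates had higher levels of the transcripts that interferon induces. Irf7, the transcription factor that drives interferon alpha genes (chromosome 7, 141262706 to 141266481, GRCm38), stood at 3422 ± 333 CPM (SD, n = 5) against 671 ± 54.1 CPM (n = 2), a log2 change of 2.46 ± 0.16 (SE). It was seen in 423 of 424 infected and 94 of 167 uninfected cells. Oasl2, an antiviral oligoadenylate synthetase relative, rose from 73.7 ± 8.44 to 1074 ± 125 CPM (log2 3.97 ± 0.22), and Usp18, a deISGylating protease that damps interferon receptor signalling, from 186 ± 39.7 to 1645 ± 155 CPM (log2 3.26 ± 0.19). Isg15, a ubiquitin-like protein (chromosome 4, 156199424 to 156200818), rose from 72.7 ± 34.7 to 748 ± 271 CPM (log2 3.48 ± 0.48). Transcripts of Rtp4 and Phf11d were seen in 90 and 130 infected cells and in 0 of 167 uninfected cells, which allows a share of up to 1.80%, and their levels were at least 21.7-fold and at least 29.7-fold higher. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Irf7 had an adjusted p of 0.000125, Oasl2 of 5.4e-05 and Isg15 of 0.0048.

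Of 11526 genes tested by edgeR, 308 were higher and 67 lower in infected plates, 1144 and 604 at an unadjusted p under 0.05. Uninfected levels of 56 of the 308 lay under the floor of 11.8 CPM. Groups did not overlap for 24.8% of the tested genes, where chance gives 9.52%. Scaling moved the median log2 change of genes with a mean log2 CPM above 5 from 0.10 to -0.00 when library sizes alone were used. DESeq2 called 953 higher and 283 lower genes, and a count of cells with 20 or more identifiers in place of summed identifiers called 338 and 269, so that higher genes made up 55.7% of its calls against 82.1%. Lower calls dropped to 13 without uninfected replicate 2, to 24 without uninfected replicate 1 and to between 19 and 41 when an infected replicate was left out, and higher calls dropped to 198 without infected replicate 3.

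**Figure D1:**
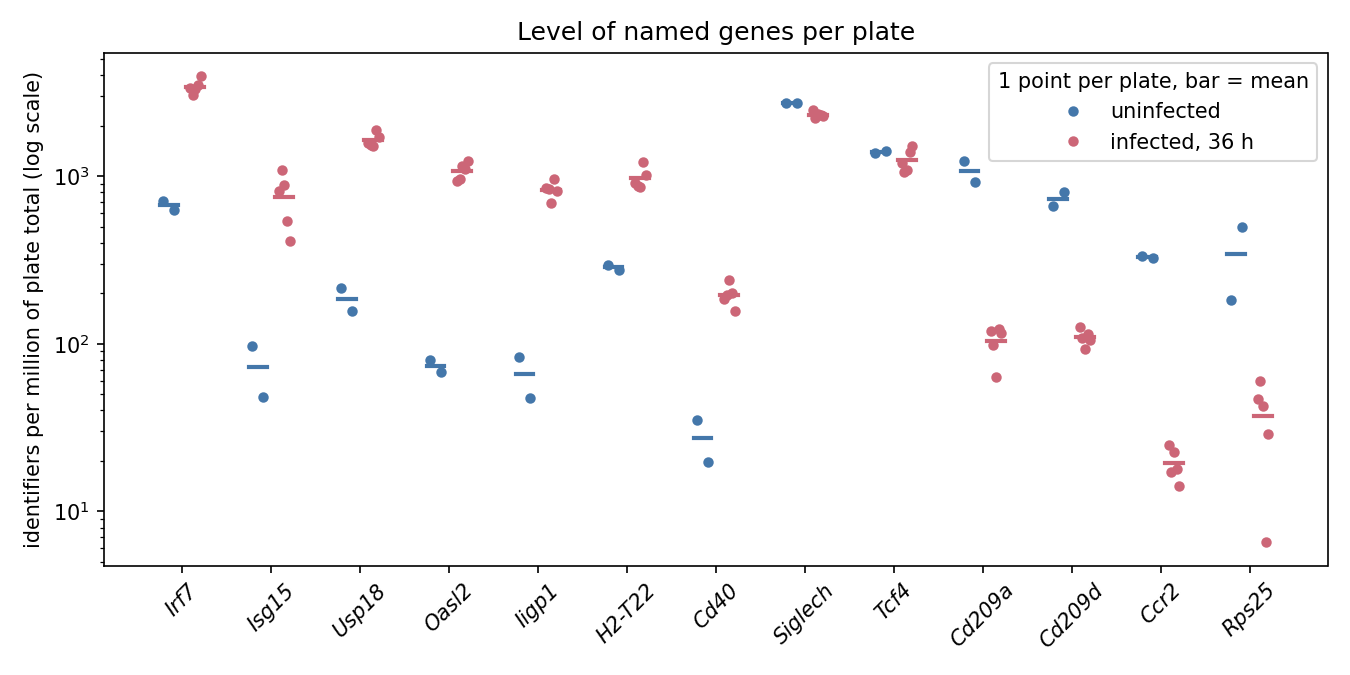
CPM of 13 named genes on each plate on a log scale, with 1 point per plate, colours for the 2 uninfected and 5 infected plates and a bar at the group mean. Irf7, Isg15 and Oasl2 sit higher on every infected plate than on either uninfected plate, while Cd209a and Ccr2 sit lower.

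Among the lists fixed beforehand, interferon-stimulated genes rose as a group. Of 48 tested members 35 were higher and 0 lower, 44 and 0 when adjusted over the list alone, with a median log2 change of 3.23, or 2.88 with genes under the floor at their bound. Camera called the list with an adjusted p of 0.00504 with an estimated correlation and Benjamini-Hochberg adjustment. Among interferon gamma-inducible GTPases and targets, 11 of 19 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 0.0292 with an estimated correlation). They included Iigp1, an immunity-related GTPase, at 830 ± 95.9 against 65.6 ± 25.7 CPM (log2 3.78 ± 0.28), and Irgm1, Igtp and Ifi47 with log2 changes of 2.22 ± 0.22, 2.82 ± 0.28 and 2.38 ± 0.25. Nucleic acid sensing had 3 higher members of 25 (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0453 with an estimated correlation). These were Irf7, Zbp1, a Z-form nucleic acid sensor (log2 2.82 ± 0.38), and Ifih1, the RNA helicase MDA5 (log2 3.29 ± 0.45). All 3 are also in the interferon-stimulated list, so their calls repeat part of that result.

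Of 19 tested transcripts of the MHC class I pathway 11 rose and 0 fell, 16 and 0 adjusted over the list alone, with a median log2 change of 0.89, and camera passed the threshold only at the preset correlation (adjusted p = 0.0826 with an estimated correlation). Among them were the nonclassical class I genes H2-T22 (log2 1.88 ± 0.19), H2-T24 (1.57 ± 0.23), H2-Q6 (1.46 ± 0.19) and H2-Q7 (1.18 ± 0.16). The members share similar sequences, so reads can be split between them. Of the 12 members of the MHC class II pathway, edgeR called 0 in either direction. At an unadjusted p under 0.05, 1 was higher and 3 lower, DESeq2 called 1 higher and 2 lower, and 1 and 2 passed adjusted over the list alone.

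Transcripts of dendritic cell maturation, NF-kB and chemokines included further higher genes. Cd40 and Cd86, which give costimulation to T cells, stood at 195 ± 30.2 against 27.3 ± 10.9 CPM (log2 2.95 ± 0.34) and 167 ± 47.9 against 25.9 ± 13.5 CPM (log2 2.81 ± 0.44). Ccr7, the receptor that guides cells to lymphoid T cell zones, stood at 137 ± 26.2 against 26.0 ± 13.9 CPM (log2 2.51 ± 0.42). Of 22 tested maturation genes 4 rose and 0 fell (9 and 0 adjusted over the list alone, median log2 1.93, or 0.53 with genes under the floor at their bound; camera adjusted p = 0.0447 with an estimated correlation). Of 23 NF-kB targets 7 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 0.0231 with an estimated correlation), among them Icam1, an adhesion molecule (log2 1.68 ± 0.23), Nfkbie, an inhibitor of NF-kB (1.18 ± 0.19), Traf1 (2.27 ± 0.39) and the survival factor Bcl2a1d, at least 3.18-fold. Traf1 is also in the maturation list. Of 15 cytokines and chemokines 3 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.0447 with an estimated correlation). These were the chemokines Ccl4 (log2 1.68 ± 0.25), Ccl5, at least 5.44-fold, and Cxcl10, at least 5.1-fold. With only the 182 infected cells inside the LIFR range of uninfected cells, edgeR called 0 members of these 3 lists. Their median log2 changes were also smaller there than in all infected cells. They were 0.31 against 1.93 for maturation (19 genes tested) and 0.62 against 1.18 for NF-kB targets (21 tested). For cytokines and chemokines the median was 2.21, over only 6 tested genes, against 8.81. Interferon-stimulated genes had a median of 2.91 there against 3.23.

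Interferon genes themselves were measured in few cells. Ifnb1, which encodes interferon beta (chromosome 4, 88522025 to 88522774), stood at 57.8 ± 10.4 CPM in infected plates and under the floor in uninfected plates, at least 4.9-fold higher, and was seen in 10 of 424 infected and 0 of 167 uninfected cells. Of 11 tested type I and III interferon genes 4 rose and 0 fell, 10 and 0 adjusted over the list alone, with a median at the bound of 1.33 on the log2 scale and a camera adjusted p = 0.121 with an estimated correlation. In the 182 infected cells inside the LIFR range of uninfected cells 1 interferon gene could be tested and 0 were called. Ifnl2 was at least 3.2-fold, Ifna5 at least 3.4-fold and Ifna9 at least 3.55-fold higher, the last 2 uncertain because interferon alpha genes are near-identical copies. Ifna4, uncertain for the same reason, stood at 26.1 ± 33.2 CPM and missed the threshold, with an adjusted p of 0.15 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

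Lists of protein folding, cell death and handling-sensitive genes also held higher members. Of 22 genes of endoplasmic reticulum folding and stress 4 rose and 0 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.118 with an estimated correlation), namely Xbp1, a factor of the unfolded protein response (log2 1.46 ± 0.22), the chaperones Hspa5 (0.96 ± 0.15) and Pdia3 (0.72 ± 0.15), and Edem1 (1.57 ± 0.35). Of 19 apoptosis genes 3 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.118 with an estimated correlation), namely Daxx (2.84 ± 0.29), Xaf1 (2.35 ± 0.26) and the inflammatory caspase Casp4 (3.63 ± 0.46). Xaf1 is also in the interferon-stimulated list. Immediate early and handling stress genes, which can respond to cell isolation, had 7 higher and 0 lower members of 23 (8 and 0 adjusted over the list alone; camera adjusted p = 0.0447 with an estimated correlation). In the infected cells inside the LIFR range of uninfected cells, which are fewer, 2 of 22 were higher, with a median log2 change of 0.35 against 0.73 in all infected cells. There 1 of 21 endoplasmic reticulum genes was higher, with a median of 0.44 against 0.50. For apoptosis 1 of 18 was higher, with a median of 0.76 against 1.02. Among the 7 were the heat shock proteins Hspa8 (1.53 ± 0.16) and Dnajb1 (2.26 ± 0.33), the signalling regulator Rgs1 (2.86 ± 0.40) and the phosphatase Dusp1, at least 6.7-fold. The largest positive fitted log2 changes included BC023105, Ddx60, an antiviral helicase, Axl, a receptor tyrosine kinase, Il12rb1, a chain of the IL-12 receptor, Tmem106a, Tnfsf9, the ligand of 4-1BB, and Gpr33. Their uninfected levels lay under the floor, with lower bounds between 3.83-fold and 9.33-fold, below those of Rtp4 and Phf11d, so the rank holds for the fitted change only.

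Genes that define pDCs changed in both directions, and few passed the threshold. Of 35 pDC identity genes 3 rose and 2 fell, 7 and 2 adjusted over the list alone, with a median log2 change of 0.25, while 13 were higher and 5 lower at an unadjusted p under 0.05 and DESeq2 called 7 and 3. The count test recovered 2.99% of simulated changes of 1 on the log2 scale, so smaller changes can be missed. Siglech, a lectin used to identify pDCs, stood at 2328 ± 93.1 against 2739 ± 7.24 CPM (log2 -0.13 ± 0.12), Tcf4, their lineage-defining transcription factor, at 1253 ± 198 against 1400 ± 28.4 CPM (-0.05 ± 0.18), Bst2 had a log2 change of 0.06 ± 0.25, Ly6d of -0.06 ± 0.19 and Ccr9 of 0.58 ± 0.16, and these did not pass the threshold, although the plates of the groups did not overlap for Siglech and Ccr9. The signs of Bst2, Tcf4 and Ly6d turned under some other settings. Lifr (chromosome 15, 7090614 to 7197489) stood at 217 ± 42.7 against 197 ± 30.1 CPM (log2 0.25 ± 0.26), with an adjusted p of 0.787 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, although infected cells had been sorted with an enrichment for low LIFR protein. Of the list, Klk1, a kallikrein protease (log2 1.09 ± 0.21), Cybb, the NADPH oxidase subunit (0.87 ± 0.17), and Grn, progranulin, rose, and Cd209d, a lectin (-2.64 ± 0.19), and Cox6a2, a cytochrome oxidase subunit (-2.97 ± 0.60), fell.

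The 67 lower genes included Ccr2 and Cd209a. Ccr2, a chemokine receptor (chromosome 9, 124101950 to 124113557), fell from 329 ± 6.51 to 19.4 ± 4.34 CPM (log2 -3.98 ± 0.29) and was seen in 12 of 424 infected and 52 of 167 uninfected cells. Cd209a, a C-type lectin (chromosome 8, 3743397 to 3748984), fell from 1078 ± 222 to 104 ± 24.8 CPM (log2 -3.26 ± 0.25). Gmfg, S100a11 and Gng5 fell with log2 changes of -3.58, -3.25 and -2.89. Of 86 cytosolic ribosomal protein genes 14 fell and 0 rose, 50 and 0 adjusted over the list alone, with a median log2 change of -1.93 and a camera adjusted p = 0.303 with an estimated correlation. They included Rps25 (-3.11 ± 0.66), Rpl37a (-3.01 ± 0.62), Rplp2 (-2.93 ± 0.52), Rpl37 (-2.80 ± 0.48), Rpl27a (-2.59 ± 0.46) and Rpl30 (-2.29 ± 0.42). Of 29 oxidative phosphorylation genes 2 fell and 0 rose, Ndufa1 (-3.33 ± 0.74) and Ndufa7 (-2.42 ± 0.52), subunits of respiratory complex I, and 21 and 0 passed adjusted over the list alone (median -2.01; camera adjusted p = 0.303 with an estimated correlation). Of 13 mitochondrially encoded genes 1 fell and 0 rose, mt-Nd6 (-2.46 ± 0.50), and 4 and 0 passed adjusted over the list alone (median -0.68; camera adjusted p = 0.303 with an estimated correlation). Infected replicates 4 and 5 held fewer ribosomal protein transcripts than the other infected plates, and without both plates 15 ribosomal protein genes fell, with a median of -1.40.

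**Figure D2:**
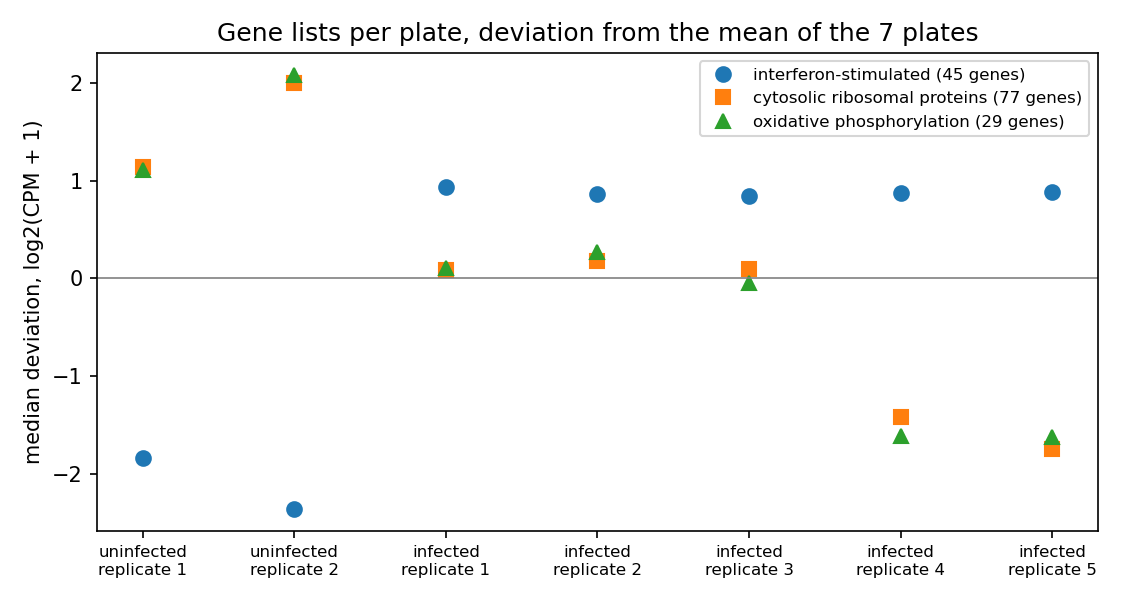
Median deviation of log2(CPM + 1) from each gene's mean over plates, per plate, for 45 interferon-stimulated, 77 cytosolic ribosomal protein and 29 oxidative phosphorylation genes, with 1 point per plate. Interferon-stimulated genes lie between 0.84 and 0.93 on the infected plates, whereas ribosomal protein genes lie at 1.14 and 2.00 on the uninfected plates and reach -1.42 and -1.75 on infected replicates 4 and 5.

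Energy metabolism and cell division lists had few calls. Of 15 glycolysis and hypoxia genes and 14 proliferation genes edgeR called 0. At an unadjusted p under 0.05, 2 glycolysis genes were higher and 0 lower, DESeq2 called 1 and 0, and 1 passed adjusted over the list alone. For proliferation the unadjusted counts were 2 higher and 2 lower, DESeq2 and the adjustment over the list alone gave 0, and the median log2 change of 0.07 turned to -0.05 with library sizes alone.

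Markers of other cell types included higher and lower genes. Of 4 B cell markers Cd79b fell (log2 -2.02 ± 0.36), of 5 plasma cell markers Fam46c rose at least 4.37-fold, of 7 T cell markers Cd8a (1.56 ± 0.30) and Cd8b1 (1.40 ± 0.24) rose, and of 3 NK cell markers Klrk1 rose (2.51 ± 0.50) and Klrd1 fell (-2.37 ± 0.36). For these lists the counts adjusted over the list alone had the same values. The T cell list was called higher by camera at the preset correlation (adjusted p = 0.0216) and by fry (adjusted p = 0.000239), and camera lost it with an estimated correlation (adjusted p = 0.118). Among conventional dendritic cell markers, Cd209a was the 1 call of 7 type 2 genes, and of 7 type 1 genes edgeR called 0, with 0 higher and 0 lower at an unadjusted p under 0.05 and 1 higher by DESeq2. Of 12 transitional dendritic cell markers Axl and Lgals3 (2.45 ± 0.35) rose and Ccr2 and S100a11 fell (3 and 3 adjusted over the list alone), and of 5 monocyte and macrophage markers Ccr2 fell (2 higher and 1 lower adjusted over the list alone). In the lists for proliferation and for B cell, monocyte and macrophage, type 1, type 2 and transitional dendritic cell markers the median log2 change, the mean log2 change or the camera direction differed in sign. No neutrophil, erythroid or platelet marker passed the expression filter. Camera called 15 of the lists at the preset correlation and 7 with an estimated correlation, and fry called 15.

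Infected cells with 0 interferon identifiers were then compared with uninfected cells, which asked what differs in cells that were not counted as making interferon. Of 11235 genes 195 were higher and 27 lower by edgeR (884 and 544 at an unadjusted p under 0.05, and 714 and 204 by DESeq2), and 33 of the higher genes lay under the floor in uninfected plates. Groups did not overlap for 22.6% of genes. Irf7 stood at 3437 ± 330 CPM (SD, n = 5) against 671 ± 54.1 CPM (n = 2; log2 2.42 ± 0.15), Oasl2 had a log2 change of 3.94 ± 0.21 and Isg15 of 3.38 ± 0.47. Of 48 interferon-stimulated genes 33 rose and 0 fell (44 and 0 adjusted over the list alone; camera adjusted p = 0.00864 with an estimated correlation), and of 19 interferon gamma-inducible GTPases and targets 9 rose (14 and 0 adjusted over the list alone; camera adjusted p = 0.0353 with an estimated correlation), with Gbp6 at a log2 change of 3.63 ± 0.44. Of 19 MHC class I genes 8 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 0.0723 with an estimated correlation).

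In these cells the maturation genes Cd40 (log2 2.54 ± 0.48) and Cd86 (2.63 ± 0.50) rose, 2 of 20 tested (3 and 0 adjusted over the list alone; camera adjusted p = 0.106 with an estimated correlation), as did the NF-kB targets Icam1 (1.62 ± 0.28) and Rel (1.71 ± 0.34) and the chemokine Cxcl10, at least 5.63-fold. Ccr7 stood at 65.9 ± 47.5 against 26.0 ± 13.9 CPM and had an adjusted p of 0.858 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Hspa8 (1.47 ± 0.15) of the handling stress list, Xbp1 (1.46 ± 0.21) of the endoplasmic reticulum list, and Daxx (2.79 ± 0.31) and Casp4 (3.56 ± 0.40) of the apoptosis list rose. At an unadjusted p under 0.05, 10 of 23, 7 of 22 and 4 of 18 tested members of these lists were higher, and 1, 1 and 0 were lower. Cd209a (-3.21 ± 0.22), Cd209d (-2.75 ± 0.22), Klrd1 (-2.37 ± 0.41) and Snx29 (-2.66 ± 0.44) fell. Of 85 ribosomal protein genes 4 fell (49 adjusted over the list alone), and of 29 oxidative phosphorylation genes 1 fell (20 adjusted over the list alone), and camera with an estimated correlation called neither list (adjusted p = 0.330 for both). Without uninfected replicate 2 the counts were 129 higher and 5 lower, without infected replicate 3 they were 128 and 9, and lower calls numbered 9 without uninfected replicate 1, 8 without infected replicate 1 and 15 without infected replicate 5. Cells counted at 20 or more identifiers gave 259 higher and 284 lower genes.

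The share of cells with interferon transcripts was measured per plate after thinning each cell to the same identifier total, which does not match plates on genes per cell or on how far identifiers saturate. On infected plates 20.4% ± 9.57 of cells (SD, n = 5) held at least 1 interferon identifier against 0.769% ± 1.09 on uninfected plates (n = 2), a difference of 19.6 percentage points with an exact two-sided permutation p of 0.0952. At least 3 identifiers were held by 8.22% ± 1.76 against 0% (27 of 330 against 0 of 143 cells, where 0 allows a share of up to 2.10%), with an exact permutation p of 0.0476, the smallest that 21 splits can give. Without thinning, 95 of 424 infected and 2 of 167 uninfected cells held at least 1 identifier, and 32 and 0 held at least 3. At least 20 identifiers were held by 18 of 424 infected cells, found on each infected plate, and by 0 of 167 uninfected cells (4.25% against 0% without thinning; exact permutation p = 0.0476), while after thinning the difference was 5.14 percentage points with an exact permutation p of 0.0952, which does not pass. Interferon values of 1 to 19 identifiers occurred in 77 infected cells, a range seen 4.73 times as often in the same well of the next plate as in its other wells where a rarely seen gene had 20 or more identifiers. That ratio was 12.0 from infected replicate 2 to 3 and 1.36 to 3.29 for the other 5 pairs of neighbouring plates, against at most 1.93 for the 30 pairs that are not neighbours, so low values alone do not show that a cell transcribed the gene.

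Within the infected plates, the 32 cells with 3 or more interferon identifiers were compared with the 329 cells with 0, per plate and with the plate as a block. Of 14 cytokine and chemokine transcripts 5 were higher and 0 lower in the interferon-positive cells (5 and 2 adjusted over the list alone), and camera did not call the list with an estimated correlation (adjusted p = 0.0855). Il12b, a chain of interleukins 12 and 23 (chromosome 11, 44400063 to 44414033), stood at 812 ± 543 CPM (SD, n = 5) against 0.156 ± 0.16 CPM and was seen in 6 of 32 positive and 0 of 329 negative cells. Il27 was seen in 6 and 0 cells and Ccl5 in 8 and 1 cells. The chemokine Ccl3 stood at 1262 ± 197 against 167 ± 63.0 CPM (log2 2.65 ± 0.36), Ccl4 at 1971 ± 738 against 581 ± 145 CPM (1.38 ± 0.22), lymphotoxin alpha (Lta) at 949 ± 737 against 84.2 ± 22.3 CPM (2.90 ± 0.53) and Cd83, a maturation marker, at 855 ± 507 against 31.4 ± 30.6 CPM (4.75 ± 0.78). Of 23 maturation genes 2 rose, Il12b and Cd83, and of 23 NF-kB targets 1 rose, again Cd83. Il12b is also among the 5 higher cytokine and chemokine transcripts. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Il12b had an adjusted p of 3.6e-05 and Ccl3 of 0.00335.

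Of 10313 genes 8 were higher, Glipr1 (log2 1.10 ± 0.20) being the last of them, and 15 lower, 40 and 3483 at an unadjusted p under 0.05. The lower genes included Siglech (-0.62 ± 0.10), Rnase6 (-0.47 ± 0.08) and Plac8 (-0.45 ± 0.08) of the pDC identity list. Outside that list were Ly6c2 (-0.43 ± 0.06), the leukotriene pathway gene Alox5ap (-1.04 ± 0.17), Arhgdib (-1.30 ± 0.21), Laptm5, Ctsb, Itm2b and Ly6e, and the class I genes B2m (-0.36 ± 0.06) and H2-D1 (-0.34 ± 0.06). The changes of these lower genes were smaller than the median log2 change of all tested genes, -4.66, or of genes with a mean log2 CPM above 5, -1.65. The positive cells numbered only 4 to 8 per plate, so genes seen in few cells can be missing from their sums. With negative cells matched on their total, the median of genes above 5 was -0.66. The medians of -4.66 and -1.65 therefore do not show how far a typical gene fell. With DESeq2's size factors or library sizes alone edgeR called 8 higher and 0 lower genes, so the lower calls of edgeR depend on the scaling. DESeq2 itself, with its own size factors, called 43 and 3479, so the counts also depend on the test. It shared 6 of the 8 higher and 0 of the 15 lower calls. Without the plate as a block the counts were 16 and 606. Counting cells with 20 or more identifiers gave 0 and 0 calls, positive cells at 1 or more identifiers gave 2 and 0, and leaving out infected replicate 1 gave 4 and 5. Interferon-stimulated genes had 0 calls of 48 (1 higher and 8 lower at an unadjusted p under 0.05, and 0 and 2 by DESeq2), and Isg15 stood at 1191 ± 443 against 719 ± 248 CPM (log2 0.38 ± 0.23). The test recovered 0% of simulated changes of 2 on the log2 scale here and 15.2% of those of 4, so 0 calls do not show equal levels. Of the 32 positive cells 18 held 20 or more interferon identifiers, and the others lay in the range that carry-over can reach. With 3 lists, for dendritic cell maturation, NF-kB targets and cytokines, as the exceptions, lists that camera called higher at the preset correlation had medians below 0.

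**Figure D3:**
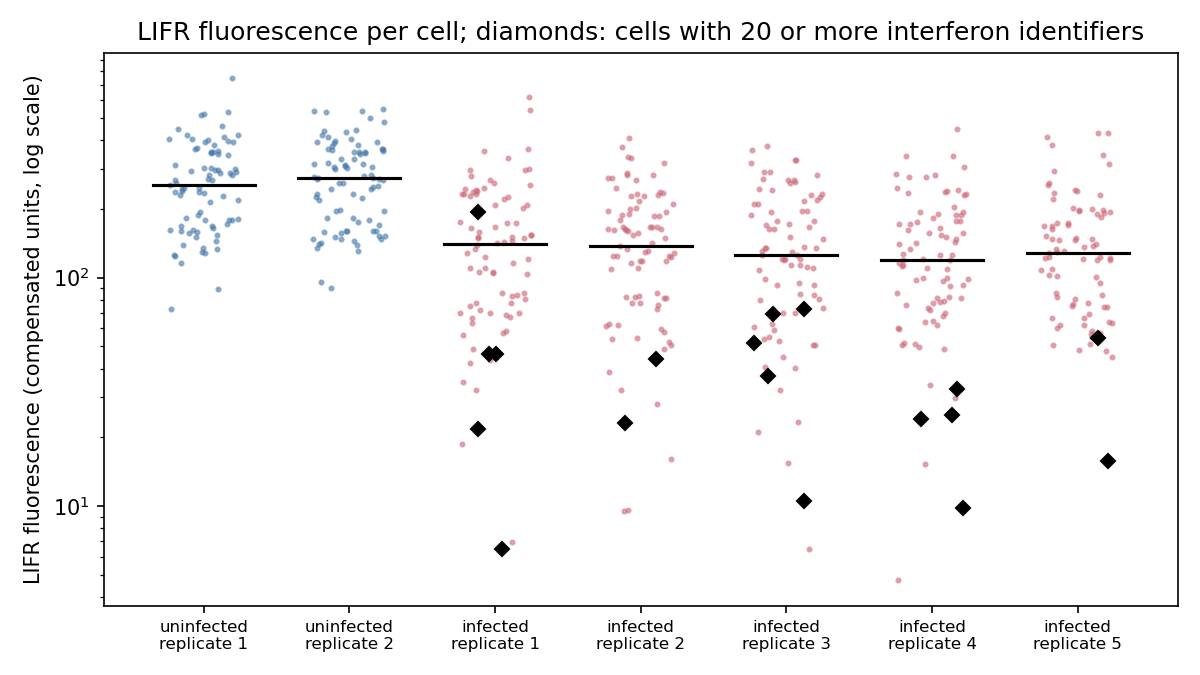
LIFR fluorescence of each of the 591 cells by plate on a log scale, with diamonds for cells with 20 or more interferon identifiers and a line at each plate's median. Plate medians lie at 253 and 273 on the uninfected plates and between 119 and 141 on the infected plates, and 17 of the 18 diamonds lie below their plate's median.

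The index sort measured surface proteins on the same cells. LIFR fluorescence had a plate median of 130 ± 8.71 units (SD, n = 5) on infected and 263 ± 14.0 units on uninfected plates (n = 2; exact two-sided permutation p = 0.0476, the smallest possible), the infected plates having been sorted with an enrichment for LIFR-low cells. BST2, a protein induced by interferon, stood at 326 ± 23.5 against 242 ± 8.70 units and CD11b at 7.27 ± 0.728 against 4.40 ± 0.596 units, each with an exact permutation p of 0.0476. Forward scatter, side scatter and the viability dye also differed with an exact permutation p of 0.0476, higher for both scatters and lower for the dye. CD11c (exact permutation p = 0.238) and the lineage cocktail (0.0952) did not pass the threshold. These 8 comparisons were not adjusted, and with an adjustment over 8 comparisons the smallest possible p does not pass. Within infected plates, LIFR fluorescence and Lifr identifiers had a median Spearman's rho of 0.229, positive on 5 of 5 plates, and LIFR fluorescence and the interferon total had a median rho of -0.193, negative on 5 of 5 plates. BST2 fluorescence and Bst2 identifiers had a median rho of 0.0345, and BST2 fluorescence and the interferon total one of 0.105. For CD11c the median rho was 0.155 with Itgax, its gene, and 0.0949 with the interferon total, and for CD11b it was 0.142 with Itgam, over 2 plates, and -0.0250 with the interferon total.

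Cells were also split at the plate's median LIFR fluorescence, a comparison chosen after the intensities had been seen. The 211 LIFR-low cells had higher levels than the 213 LIFR-high cells of the same plates for 7 of 10858 genes. Ifnb1 stood at 116 ± 22.5 CPM (SD, n = 5) against 0.067 ± 0.0986 CPM and was seen in 10 and 0 cells, Il27 in 7 and 0 cells and Il12b in 6 and 0 cells. Ccl4 stood at 1028 ± 120 against 426 ± 112 CPM (log2 1.33 ± 0.12), Glipr1 at 1009.7 ± 127 against 444 ± 46.4 CPM, and Cd82, a tetraspanin, had a log2 change of 1.08 ± 0.11 and Plaur, the urokinase receptor, of 0.78 ± 0.09. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Ccl4 had an adjusted p of 0.021 and Ifnb1 of 0.0283. Adjusted over the list alone, 10 of 11 interferon genes, 12 of 23 NF-kB targets, 6 of 14 cytokines and chemokines, 4 of 22 maturation genes and 10 of 48 interferon-stimulated genes were higher, and 7 of 35 pDC identity genes lower, against 1, 0, 3, 1, 0 and 0 over all genes. With an estimated correlation, camera gave adjusted p = 0.131 for interferon genes, 0.0707 for NF-kB targets and 0.2 for interferon-stimulated genes. Lifr itself stood at 149 ± 48.3 against 284 ± 66.7 CPM (log2 -0.96 ± 0.27) and missed the threshold.

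By edgeR 0 genes were lower in LIFR-low cells, 250 were at an unadjusted p under 0.05, and DESeq2 called 469 higher and 423 lower. Leaving out any 1 infected replicate, or the cells with 20 or more interferon identifiers, gave 0 calls by edgeR in either direction. Without the plate as a block the counts were 17 higher and 2 lower, and with values under 20 set to 0 they were 77 and 15.

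Clustering of all cells gave 4 clusters. Cluster 0 held 156 uninfected and 14 infected cells and was led by Cd209a, Cox6a2 and Ccr2. Clusters 1 and 2 held 127 and 163 infected cells with 6 and 5 uninfected cells. Cluster 3 held 120 infected and 0 uninfected cells, between 22.99% and 34.5% of each infected plate, and was led by Lta, Ccl3, Tnf and Cd40. The clusters were left unnamed. Median LIFR fluorescence in cluster 3 lay 87.7 ± 15.9 units (SD, n = 5) under that of the other infected cells, lower on 5 of 5 plates, with an exact two-sided p of 0.0625, the smallest that 5 plates can give. Cluster 3 was taken for its lowest difference. By the same test cluster 2 lay 49.2 ± 24.8 units higher, lower on 0 of 5 plates (exact p = 0.0625), and cluster 1 28.4 ± 37.2 units higher (exact p = 0.188).

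Cell content was compared between the groups by plate medians. Identifiers per cell differed by -31528 (infected minus uninfected; exact two-sided permutation p = 0.0952), with plates at 161097 to 203488 against 214598 to 229532.5 and no overlap, and genes per cell by 117 (exact permutation p = 0.714), or by 12.9 to 192 with 1 plate left out. The mitochondrial share of identifiers was 0.948% ± 0.130 on infected plates (SD, n = 5) and 1.495% ± 0.205 on uninfected plates (n = 2), with an exact permutation p of 0.0476, the smallest possible.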

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

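The tests for a plate effect and in the LIFR range of uninfected cells were chosen after the data had been seen. In 110 groups of plate values examined for a plate far from the others, 2 stood out, where chance gives about 1 in 20, or 5.5. Axl, a receptor tyrosine kinase, stood at 92.2 CPM on infected replicate 2 against 52.4 to 63.1 CPM on the other infected plates. Dnajb1, a heat shock protein, stood at 677 CPM on infected replicate 5 against 458 to 507 CPM on the others.

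Transcripts of cytosolic ribosomal proteins and of oxidative phosphorylation had median log2 changes of -1.93 and -2.01 on infected plates, where 14 of 86 and 2 of 29 members fell and camera with an estimated correlation called neither list (adjusted p = 0.303 for both). Transcript length bias argues poorly for the whole pattern, since both lists lay below genes matched on length and level, by -1.91 (95% bootstrap interval over genes -2.22 to -1.33) and -1.78 (-2.04 to -1.46) on the log2 scale. These intervals do not measure the spread between plates. With the length trend taken out the medians were -1.60 and -1.40, so length can account for part of both changes. A plate effect stays open as a candidate explanation for part or all of the pattern. Ribosomal protein genes also differed by -1.71 between infected replicates 4 and 5 and the other infected plates, which share the condition. Infected replicates 1 to 3 still lay below uninfected plates by -1.36, but the uninfected plates also differed from each other, with median deviations of 1.14 and 2.00. Oxidative phosphorylation genes differed by -1.85 between the same sets of infected plates. For them infected replicates 1 to 3 lay below uninfected plates by -1.41, with the uninfected plates at 1.11 and 2.09. In infected cells inside the LIFR range of uninfected cells the medians were -1.93 and -1.99, with 3 of 84 and 3 of 29 members called among fewer cells, which argues against the sort as the main source, while infection stays open and was not separated from the plate effect.

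The interferon response of infected plates was weighed against the sort for LIFR-low cells and against chance. In the 182 infected cells whose LIFR fluorescence lay between the 10th and 90th percentile of uninfected cells, 88.4% of the median log2 change of the 35 called interferon-stimulated genes was left, and 30 of them kept their call, which argues against the sort as the main source. Of the 21 splits of the plates into 2 and 5, only 1, the labelled one, gave as many as its 375 called genes. The highest other split gave 0, and each other split mixes infected with uninfected plates. The labelled split thus ranked first at a share of 0.0476, the smallest that 21 splits can give. That share concerns a random assignment of plates to groups and not a batch that infected plates have in common. Between the infected plates low in ribosomal protein transcripts and the other infected plates, interferon-stimulated genes differed by a median of 0.13 on the log2 scale. Ribosomal protein genes differed by -1.71 there. Interferon-stimulated genes lay above uninfected plates by 3.22 and 3.19 in these sets of plates. This argues against the plate effect seen in ribosomal protein genes as the source of the interferon response. A response to infection remains a hypothesis that these values allow. A batch difference common to all infected plates was not separated from it, since it would move every infected plate alike.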

How the results depend on the processing

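Settings with values under 20 set to 0, a count of cells at 20 or more identifiers, a saturation correction, a length trend taken out, a LIFR range, infected replicates 4 and 5 left out, positive cells and shares at 20 or more identifiers, left-out plates for cell content, and all settings of the LIFR comparison and of LIFR by cluster were chosen after the data were seen. For infected against uninfected plates, the counts of higher and lower genes were within 1.5 times of 308 and 67 with DESeq2's factors, library sizes alone, no filter on low counts, other gene minimums, values under 20 set to 0, the saturation correction and the length trend. DESeq2 called 953 and 283, thinned cells gave 38 lower, cells at 20 or more identifiers 269 lower, the set without plates 6 and 7 204 higher, and the LIFR range 118 and 11. Leaving out cells holding other-type markers took out 559 of the 591 cells. Infected replicate 3 dropped out, 2 to 14 cells were left on each other plate, and 5 higher and 0 lower genes remained by edgeR. Leaving out 1 plate gave 198 to 258 higher and 13 to 41 lower genes.

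For interferon-negative infected cells, DESeq2 called 714 and 204, cells at 20 or more identifiers gave 284 lower, the set without cells holding other-type markers 4 and 0, and leaving out 1 plate 128 to 180 higher and 5 to 23 lower. For interferon-positive cells, DESeq2 called 43 and 3479, and edgeR called 0 lower genes with DESeq2's factors and with library sizes alone, 34 lower without a filter, 33 with thinned cells, 133 with values under 20 set to 0, 9 with the saturation correction, and 0 and 0 with cells at 20 or more identifiers. Positive cells at 1 or more identifiers gave 2 and 0, at 10 or more 19 and 2245 and at 20 or more 22 and 59, negative cells matched on their total 13 higher, and leaving out 1 plate 4 to 9 higher and 5 to 24 lower, with the counts at 4 and 5 without infected replicate 1, 9 and 24 without infected replicate 2, 5 and 23 without infected replicate 4 and 5 and 6 without infected replicate 5. The fit with no replicate block for the plate gave 16 and 606. For LIFR-low against LIFR-high cells, DESeq2 called 469 and 423, and edgeR 4 higher with thinned cells, 3 lower with cells at 20 or more identifiers, 77 and 15 with values under 20 set to 0, 18 higher with the saturation correction, 11 higher for the lowest against the highest of 3 equal parts, 17 and 2 with no replicate block, 0 higher without cells of 20 or more interferon identifiers, and 0 to 0 leaving out 1 plate. The cause was not tested for these values. No paired analysis was possible because the replicate numbers of infected and uninfected plates name separate plates that do not pair.

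The gene lists called by camera fell from 15 to 7 with an estimated correlation. The interferon share difference at 1 or more identifiers was 16.9 to 22.1 points leaving out 1 plate. At 3 or more identifiers, where no plate was left out, it was 8.22 points, past the threshold. The difference in mitochondrial share ran from -0.692 to -0.402 leaving out 1 plate, where the exact permutation test cannot pass, since its smallest p with 6 plates is 0.0667 or 0.167. In cells with 1 or more identifiers the median rho was 0.130 for LIFR with Lifr, negative on 2 of 5 plates. It was -0.408 for LIFR and 0.265 for BST2 with the interferon total. The sign turned from 0.0949 to -0.152 for CD11c and from -0.0250 to 0.101 for CD11b with the interferon total, and from 0.155 to -0.214 for CD11c with Itgax. A resolution of 1.2 gave 9 clusters, and the cluster led by Lta at 0.8 (120 cells) is not the one led by Ifnb1 and Lta at 0.5 (45 cells, LIFR lower by -83.5) and at 1.2 (48 cells, -82.1). At 1.2 another cluster was lower by -53.1 on 5 of 5 plates and another by -29.8 on 4 of 5.

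Among named genes, signs turned only in comparisons where the gene had missed the threshold. Over infected plates Bst2 ran at -0.056 with library sizes, -0.036 for cells at 20 or more, -0.0076 with the saturation correction and -0.053 to 0.18 leaving out 1 plate, Lifr at -0.029 and -0.025 for cells at 20 or more and the length trend, and Siglech at 0.15 without other-type cells. Ly6d ran at 0.18 without other-type cells, 0.21 with the length trend, 0.16 without plates 6 and 7 and -0.12 to 0.066 leaving out 1 plate, and Tcf4 at -0.14 to 0.0048. Over interferon-negative cells Bst2 ran at -0.036 with library sizes, -0.0066 without a filter, -0.11 for cells at 20 or more, -0.0014 with values under 20 set to 0, -0.018 with the saturation correction and -0.099 to 0.23 leaving out 1 plate. Ccr9 ran at -0.061 for cells at 20 or more, Lifr at -0.12 for cells at 20 or more, -0.070 with the length trend and -0.040 to 0.34 leaving out 1 plate, Ly6d at 0.15 without other-type cells, 0.26 with the length trend, 0.20 without plates 6 and 7 and -0.12 to 0.062 leaving out 1 plate, and Siglech at 0.19 without other-type cells. In interferon-positive cells Cd86 ran at 0.23 by DESeq2 and with its factors, 0.27 with library sizes, 0.048 thinned, 0.90 for cells at 20 or more and 0.52 with no replicate block. It ran at 0.19, 1.00 and 1.53 for positive at 1 or more, at 20 or more and matched cells, and -0.81 to 0.81 leaving out 1 plate, and Isg15 at -0.018 for cells at 20 or more. In LIFR-low cells Irf7 ran at 0.0017 with the saturation correction, 0.0073 for the outer of 3 parts, 0.0002 without interferon-high cells and -0.014 to 0.0093 leaving out 1 plate, and Ly6d at -0.020 for cells at 20 or more. Of 73 named genes called between infected and uninfected plates, 39 kept their call under each left-out plate. Under the other settings 7 kept it wherever they could be tested. Without cells holding other-type markers only 2 kept their call, 47 lost it and the rest could not be tested. That setting took out 559 of the 591 cells, so a lost call there does not show that other cell types carried it. Scaling to spike-ins, identifiers per spike-in and annotated states were not run. Genes near the floor of 11.8 CPM are limited by depth.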

Other observations

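The cells with 20 or more interferon identifiers were chosen after their values were seen, as were the genes named for them; the carry-over test was chosen after its result was seen, and the depth test before. Of these 18 infected cells, 10 held 20 or more identifiers of Ifnb1, a gene that is part of their definition. Outside that definition they held the cytokine transcripts Il12b (6 of 18 against 0 of 406), Il27 (6 against 1) and Tnf (11 against 36), the chemokines Ccl3 (14 against 64), Ccl4 (16 against 142) and Ccl5 (8 against 2), lymphotoxin alpha Lta (11 against 25), the maturation marker Cd83 (10 against 14) and the orphan nuclear receptor Nr4a1 (7 against 12). Among interferon alpha genes, also part of the definition and uncertain in their single values, Ifna5 was held by 7, Ifna9 by 6 and Ifna2 by 5 cells, and Ifnl2, an interferon lambda gene, by 5.

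These 18 cells had a median LIFR fluorescence of 34.7 units against 133 units in the other infected cells, and 17 of 18 lay below their plate's median (two-sided permutation within plates p = 1e-05, the smallest that 100000 resamples can give). Their BST2 fluorescence had a median of 453 against 318 units (permutation p = 8e-05). These permutations within plates take cells as the units, so their p-values measure the spread between cells and not between plates. Depth of the cell cannot be told apart as a contribution to their low LIFR: the median rank of their cell totals within the plate was 0.593, where 0.5 would be the middle, and the permutation p was 0.254. Their totals were all at least 157333, above the thinning depth of 150800. After thinning, 17 infected cells still held 20 or more interferon identifiers, which argues against depth as what defines most of the 18. LIFR was not compared again after thinning. Some low interferon values in other wells may come from carry-over between wells with the same barcode on neighbouring plates. Where a rarely seen gene had 20 or more identifiers in a well, values of 1 to 19 of that gene were 4.73 times as frequent in the same well of the next plate as in its other wells (8.89% against 1.88%). The pair of infected replicates 2 and 3, at 12.0 times (37.1% against 3.10%), carries much of this, and the other 5 pairs lay at 1.36 to 3.29 times. The 30 pairs of plates that are not neighbours had a median of 1.17 and a maximum of 1.93, so not every neighbouring pair lies beyond that background. For values of 20 or more the ratio was 1.09. Each of the 18 cells has at most 1 well with its barcode on the next plate, and 77 infected cells held interferon values of 1 to 19. Carry-over from the 18 cells to the next plate can therefore cover only a smaller part of the 77. No biological explanation was tested for the low LIFR of the 18 cells.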
